A study of Homo sapiens with 68 samples.

How the data were processed

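Single-nucleus RNA sequencing had been done on spinal cord segments C6 (cervical), T4 (thoracic) and L4 (lumbar) of 1 tissue donor. Per the labels' protocols, nuclei were freed by homogenization, cleaned on a density gradient and placed 1 per well in plates of 384 wells, and libraries were made with a modified SCRB-seq protocol, a plate-based chemistry that tags the 3' end of transcripts with a well barcode. The labels list 68 plates, of which 25 are cervical, 20 thoracic and 23 lumbar. Values were analysed for 24 cervical, 18 thoracic and 23 lumbar plates (65 plates, 24960 wells). The tables hold 2 further plates whose names match no label, and these were not used. Plates of a segment are libraries from the same piece of tissue, so every p-value below measures plate-to-plate spread within 1 donor, which may be technical, and not the spread between people. Each plate holds nuclei of a single segment and the labels give no dissection, preparation or sequencing batch, so segment and batch cannot be told apart.

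The authors deposited whole-number counts per gene and well, not normalized. Per the submitters' processing notes, reads were aligned with STAR 2.7.8 to GRCh38. The counter, the annotation, the treatment of molecular identifiers and the strand setting are not given in the sources used here. Whether a count is a read or a molecule is therefore open, and all intervals and limits of a count of 0 below cover counting error only. Plates of a segment differed far beyond counting noise (chi-square per degree of freedom of at least 212 for each pair of plates), and 0 pairs held identical values. The count tables list 18732 gene symbols in any table and 16845 in all of them. Symbols listed more than once (9) were left out, as were genes of the sex chromosomes that could describe a person, which left 16809 genes. A share of 0.106% of cervical, 0.106% of thoracic and 0.102% of lumbar counts lay in table lines that name no gene and was left out of library sizes and tests. Mitochondrial genes carry no prefix in these tables (COX2 and COX3 are the mitochondrial genes). Of the genes used, 16084 match exactly 1 gene of GENCODE release 29, from which coordinates were taken. Reads of near-identical copies may be split or shared by the counting, which makes HSPA1A and HSPA1B, the HLA genes, ACTB, FTL, RPL18 and the mitochondrial genes uncertain. Reads of overlapping and antisense genes cannot be told apart.

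Wells of a plate shared a background. Wells with at least 500 genes detected but fewer than 60 genes at 32 or more counts were taken as background wells. Their mean count per gene was taken as the plate's background. It made up a median of 8.13% of a plate's counts in cervical, 11.6% in thoracic and 7.99% in lumbar plates. Across genes within a plate, the background correlated with the plate's summed counts (median r of 0.955, 0.976 and 0.952), genes not being independent replicates. Screened counts keep a gene's count in a well only where it exceeds 5 times the plate's background for that gene plus 10 counts. The screen kept a median of 88.8% of counts in cervical, 79.6% in thoracic and 89.3% in lumbar plates. Wells were kept as nuclei with at least 500 genes detected, under 10% mitochondrial counts and at least 100 genes above the screen. This left 7340 cervical (79.6% of wells), 4859 thoracic (70.3%) and 6939 lumbar nuclei (78.6%), or 19138 in all. Scrublet marked 0.163% of cervical, 0.206% of thoracic and 0.173% of lumbar nuclei as doublets, and no nucleus was removed as a doublet. Leaving out the 5% of nuclei with the highest scores was an alternative.

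Nuclei were clustered on log-normalized screened counts with 2000 variable genes (HOX genes left out), 30 principal components, 15 neighbours and the Leiden method at resolution 1, which gave 20 clusters. The design had called for clustering the counts as deposited. That gave 47 clusters, of which 28 held over 90% of their nuclei from a single plate (3787 nuclei). The background screen and the minimum of 100 genes above it were added after the data had been seen, and the clustering as deposited was kept as an alternative. That alternative did not apply the minimum and held 24542 nuclei, so it changed both the clustering and the nuclei kept. A cluster was named by the fixed marker list with the largest share of members at 2-fold or more over the median cluster and in at least 10% of its nuclei. It needed 3 such members and stayed unnamed where other markers outnumbered its own among its 10 leading genes. A cluster with 5 or more such members of a second list was set aside as mixed. Names mean that a cluster is like the type, for example oligodendrocyte-like, and are shortened below.

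For gene tests, counts as deposited were summed per plate and class over plates with at least 10 nuclei of that class. Each class was fitted with all 3 segments in 1 model by edgeR's quasi-likelihood test with TMM normalization, edgeR's expression filter and Benjamini-Hochberg (BH) adjustment over the genes tested. A gene was called at an adjusted p below 0.05 and a change of at least 1.5-fold. Log2 fold changes are given with standard errors (SE), and levels as library-size scaled counts (CPM), mean ± SD over plates. Neurons and vascular cells reached 10 nuclei in too few plates for gene tests. The genes to be named were, per comparison, the 4 with the largest change in each direction among called genes at a mean of at least 20 CPM with a plain symbol, up to 4 called members of each gene list, and every HOX gene tested. Genes called with both count sets, deposited and screened, are named in addition and were chosen after their values had been seen, as were the markers of other cell types whose levels are given. The 23 gene lists were tested with camera (limma) over lists with at least 3 members tested, with a preset correlation of 0.01 and again with an estimated correlation. Shares of nuclei per plate, over plates with at least 50 nuclei, were compared by two-sided permutation tests of the difference in means with 100000 resamples, BH-adjusted over the 18 planned tests, and pooled shares carry exact Clopper-Pearson 95% intervals. A share of 0 is given with the upper limit that 3 counts of the total allow, and for kinds of neuron with that of the exact interval. These choices, the gene lists and the cell type markers were made before the data were examined, except where the text says otherwise.

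The tests were tried on simulated counts for each of the 12 comparisons, with 200 genes changed. For oligodendrocytes, lumbar against cervical, with 15967 genes, 55% of 2-fold and 90% of 4-fold changes were recovered and 2 unchanged genes were called. For oligodendrocyte precursors, cervical against thoracic, with 10281 genes, the recovery was 5% and 43%, with 0 unchanged genes called. The simulated counts were drawn gene by gene from the fitted spread, without a background shared within a plate. Regrouped real plates called a median of 194 genes in the latter comparison, so the simulation does not give the rate of false calls in the real data. Alternatives were DESeq2, RLE normalization, no expression filter, a block for the plate number, only the 2 segments compared, nuclei thinned to 30000 counts, at least 1000 genes per nucleus, at least 20 nuclei per plate, Scrublet scores, Leiden resolution 0.5, the clustering as deposited, screened counts and counts with the background subtracted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.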

Results

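The data are counts of 16809 genes in single nuclei of the C6, T4 and L4 segments of the human spinal cord, sorted into 24 cervical, 18 thoracic and 23 lumbar plates of 384 wells. Total counts per plate lay between 51602664 and 83582256 in cervical, 47807342 and 71360737 in thoracic and 54837024 and 81910882 in lumbar plates. Kept nuclei held a median of 150699 counts and 6625 genes in cervical, 155887 counts and 8039 genes in thoracic and 136857 counts and 6209 genes in lumbar segments. The comparisons address how cell makeup and expression within a cell class differ between levels of the cord. All plates come from 1 donor, so the tests below compare the plates of 3 tissue pieces. A difference between segments cannot be told apart from a difference in dissection, nuclei preparation or library batch.

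Clustering on screened counts gave 20 clusters of the 19138 kept nuclei. Fixed markers named oligodendrocyte-like (3758 cervical, 2031 thoracic and 3322 lumbar nuclei), astrocyte-like (1351, 913 and 1546), microglia-like (1461, 837 and 1399) and precursor-like nuclei (393, 303 and 428). Fibroblast-like, Schwann-like, endothelial, lymphocyte-like, neuron-like and ependymal-like nuclei formed smaller clusters. 1 cluster of 161 nuclei took no name, and 1 of 140 nuclei carried markers of more than one class.

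Oligodendrocyte-like nuclei, the myelin-forming cells of the cord, were the most frequent class in every segment, with astrocyte-like and microglia-like nuclei next. All shares are of kept nuclei, and the minimum of genes above the screen removed a larger part of thoracic wells. Of wells that met the other limits, it kept 4859 of 6855 thoracic, 7340 of 9031 cervical and 6939 of 8656 lumbar ones. No alternative varied this minimum alone, so its effect on the shares below was not tested. Oligodendrocytes made up 51.2% ± 2.31 (SD, n = 24 plates) of nuclei on cervical, 41.9% ± 3.71 (n = 18) on thoracic and 47.9% ± 2.43 (n = 23) on lumbar plates. The share was 9.23 percentage points higher on cervical and 5.97 points higher on lumbar than on thoracic plates (permutation p = 1e-05 for both, the smallest the resamples can give, BH-adjusted p = 6e-05). The difference of cervical from thoracic plates was 4.13 points among the 4 glial classes alone. It was 27.8 with clustering on counts as deposited, which also changed the nuclei kept and gave 24.8 for lumbar plates. The share was lower on lumbar than on cervical plates by a difference of -3.26 points (adjusted p = 0.000144, permutation test). Astrocytes, which support neurons and synapses, made up 22.3% ± 1.66 of lumbar, 18.4% ± 2.06 of cervical and 18.9% ± 3.32 of thoracic nuclei. The lumbar share exceeded the cervical one by 3.86 points (permutation test, adjusted p = 6e-05) and the thoracic one by 3.41 points (adjusted p = 0.000135), and cervical and thoracic plates were not told apart (difference -0.447, adjusted p = 0.711). Microglia, the resident macrophages, made up 20.0% ± 2.00 of cervical, 17.3% ± 2.08 of thoracic and 20.1% ± 2.20 of lumbar nuclei. Cervical plates lay above thoracic ones (permutation test, adjusted p = 0.00021), as did lumbar plates, by 2.83 points (adjusted p = 0.000309). Lumbar and cervical microglia shares were not told apart (difference 0.133, permutation test, adjusted p = 0.93).

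Oligodendrocyte precursors made up 5.34% ± 1.13 of cervical, 6.22% ± 1.43 of thoracic and 6.20% ± 1.20 of lumbar nuclei, and the cervical share was lower than the thoracic (difference -0.876, permutation test, adjusted p = 0.0489) and the lumbar one (0.851, adjusted p = 0.0246). The first call was lost without thoracic plates 1 and 2 (-0.742, permutation test, adjusted p = 0.101). Its sign turned with clustering on counts as deposited, which also changed the nuclei kept (0.258). Among the 4 glial classes the difference was -1.78 (adjusted p = 0.00117, permutation test). The second was lost with that clustering (0.585, adjusted p = 0.059) and among the 4 glial classes (0.792, adjusted p = 0.0631) in the permutation test. Vascular nuclei made up 0.204% ± 0.252 of cervical, 0.604% ± 0.652 of thoracic and 0.614% ± 0.424 of lumbar nuclei, a share higher on lumbar than cervical plates by 0.411 points (permutation test, adjusted p = 0.000405) and lower on cervical than thoracic ones (-0.401, adjusted p = 0.0104). Neurons were rare, with 22 of 7340 cervical (0.300%, exact 95% interval 0.188 to 0.453%), 6 of 4859 thoracic (0.123%, 0.0453 to 0.269%) and 11 of 6939 lumbar nuclei (0.159%, 0.0792 to 0.283%). Their share per plate was 0.179 points higher in cervical than thoracic plates (permutation test, adjusted p = 0.0246). The lumbar share was not told apart from the cervical (difference -0.137, adjusted p = 0.0761) or the thoracic one (0.0429, adjusted p = 0.711) in the permutation test. Excitatory markers named 14 of 22 cervical, 5 of 6 thoracic and 5 of 11 lumbar neurons, inhibitory markers named 5, 1 and 3, and 3, 0 and 3 had no single kind. As cholinergic, the kind of motor neurons, 0 were named (exact 95% upper limits 15.4%, 45.9% and 28.5%), with 3 of 6 fixed markers in the tables. These counts are too few for a comparison of neuron kinds.

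**Figure D1:**
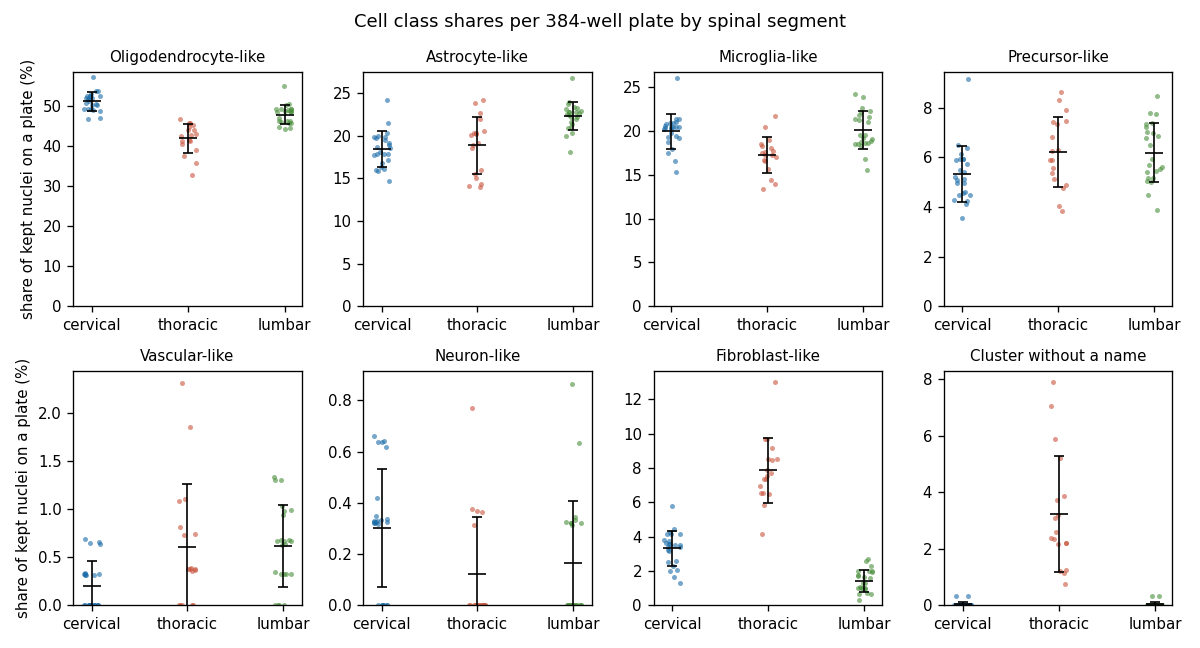
Share of kept nuclei (%) on each plate for 8 groups of nuclei, with 1 point per plate and a bar for the mean and SD over 24 cervical, 18 thoracic and 23 lumbar plates. Oligodendrocytes averaged 41.9% on thoracic plates against 51.2% on cervical ones, while fibroblast-like nuclei averaged 7.86% on thoracic plates, so that shares of the other classes are shares of a total that also holds these cells.

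Shares add up to a whole, and thoracic plates held more fibroblast-like nuclei (7.86% ± 1.89) than cervical (3.32% ± 1.01) or lumbar plates (1.43% ± 0.647). Among the 4 glial classes alone, 4 differences from thoracic plates lost their call in the permutation test. These were oligodendrocytes (lumbar, -0.128 points, adjusted p = 0.891), astrocytes (lumbar, 0.794, adjusted p = 0.447) and microglia (cervical, 0.529, adjusted p = 0.582, and lumbar, 0.323, adjusted p = 0.778). The cervical astrocyte share was lower than the thoracic one there (-2.88, permutation test, adjusted p = 0.00211). With clustering on counts as deposited, which also changed the nuclei kept, the differences of astrocytes between cervical and thoracic (4.03) and of microglia between lumbar and cervical plates (-12.9) turned sign. Both were called there (permutation test, adjusted p = 9e-05 and 3.6e-05). Microglia between lumbar and thoracic plates lost their call there (0.0350, permutation test, adjusted p = 0.994). Thoracic plates also held 106 of the 140 nuclei with markers of more than one class, of which 72 came from a single plate, and 34 without it.

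Lumbar and cervical microglia differed in 458 of the genes tested, of which 255 were higher in lumbar plates and 203 lower (edgeR quasi-likelihood, BH). SIPA1L1, which codes for a GTPase-activating protein of the small GTPase Rap (GRCh38, GENCODE release 29, chromosome 14, 71320449 to 71741229), reached 1194 ± 237 CPM in lumbar and 530.1 ± 187 CPM in cervical microglia, a log2 fold change of 1.17 ± 0.12 (SE, edgeR adjusted p = 5.61e-10, n = 23 and 24 plates). PADI2, an enzyme that turns arginine into citrulline in proteins, was higher by 0.88 ± 0.12 (1690 against 918.3 CPM, edgeR adjusted p = 5.39e-07). The signalling genes SYTL3, MAP3K8, GNA13 and CREM, the latter a cAMP-responsive transcription factor, were higher by 1.34, 1.06, 0.97 and 1.17. NAMPT, which makes a precursor of NAD, was higher by 0.95, and the phagocyte genes MSR1, a scavenger receptor, and SLC11A1, a metal transporter of phagosomes, by 0.73 and 0.78. SYNDIG1, named for a role in synapse development, and SH3RF3 were lower in lumbar microglia, with SYNDIG1 at 579.8 ± 181 against 1146 ± 377 CPM (-0.98 ± 0.15, edgeR adjusted p = 1.16e-05).

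Hypoxia genes were higher in lumbar microglia. Of the 12 members of the list tested, 9 were higher in lumbar plates, 4 were called (5 when adjusted over the list alone), and the median log2 fold change was 0.83 (camera adjusted p = 8.59e-09, and 3.52e-07 with an estimated correlation). The called members were VEGFA, the growth factor of blood vessels (2.14 ± 0.52), HILPDA, a lipid droplet protein (1.71 ± 0.33), the peptide hormone gene ADM (1.02 ± 0.28) and PFKFB3, which drives glycolysis (0.85 ± 0.14, 741.4 against 411.7 CPM). The median mitochondrial share over nuclei of every class was 0.277% in lumbar and 0.505% in cervical segments. The myelin list, markers of another cell type, was lower in lumbar microglia (median -0.28, 11 of 13 members lower, camera adjusted p = 1.46e-09). The extracellular matrix list (17 members, median -0.16, adjusted p = 0.0256, camera) and the neurofilament list (7 members, -0.32, adjusted p = 0.0256) were lower as well. The called genes with the largest changes at a mean above 20 CPM were FOSL2, SH3BP5, SDC2 and TFRC, higher by 2.28 to 2.46, and FECH, FAM160B1, GPN3 and MLF1, with -1.52 to -2.15. With screened counts 19 genes were called, 14 higher and 5 lower, and 17 of these were among the 458. There 302 of 8423 genes tested had an unadjusted p below 0.05, fewer than chance alone would give. The hypoxia list kept its call there (8 members, median 0.72, camera adjusted p = 8.55e-06), with PFKFB3 called (0.74), VEGFA at 2.17 and not called, and HILPDA and ADM not tested, and the myelin, matrix and neurofilament lists did not.

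**Figure D2:**
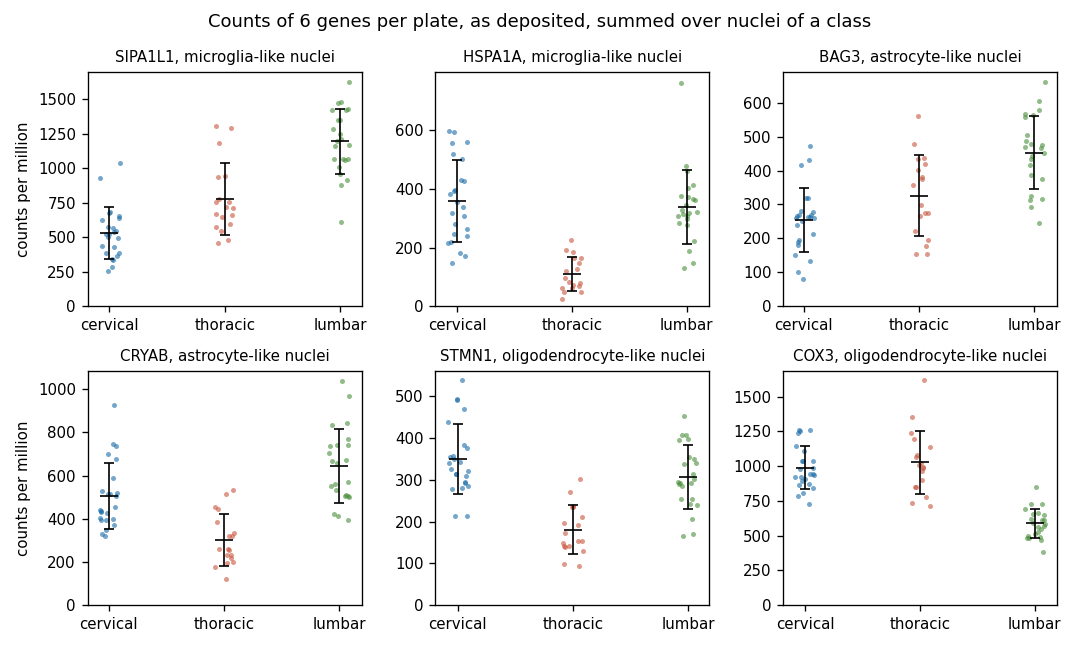
Level of 6 genes (CPM) in nuclei of a class summed per plate, with 1 point per plate and a bar for the mean and SD over 24 cervical, 18 thoracic and 23 lumbar plates. SIPA1L1 averaged 1194 CPM in lumbar and 530.1 CPM in cervical microglia, and HSPA1A averaged 109.8 CPM in thoracic microglia against 360 CPM in cervical ones.

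Lumbar and cervical astrocytes differed in 196 genes, 74 higher and 122 lower in lumbar plates (edgeR quasi-likelihood, BH). BAG3, a partner of the chaperone HSP70, was at 452.7 ± 108 CPM in lumbar and 254.1 ± 95.3 CPM in cervical astrocytes (log2 fold change 0.83 ± 0.15, edgeR adjusted p = 0.000331). F3, which codes for tissue factor, was higher by 0.85 ± 0.18 (228.2 against 126.8 CPM, edgeR adjusted p = 0.00475), and CHST15, a sulfotransferase of chondroitin sulfate, by 1.06 ± 0.22. LAMA2, a laminin chain of the basement membrane, was lower in lumbar astrocytes (337.3 ± 95.4 against 532 ± 139 CPM, -0.66 ± 0.12, edgeR adjusted p = 0.000507), as was the cell adhesion gene FLRT2 (-0.85 ± 0.18). LAMA2 is also among the leading genes of the fibroblast-like cluster.

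Among the fixed lists, 11 of 12 hypoxia genes were higher in lumbar astrocytes, with 2 called, VEGFA (84.1 ± 42.9 against 33.1 ± 23.5 CPM, 1.35 ± 0.30) and HILPDA (0.66 ± 0.17), and 3 when adjusted over the list alone (median 0.56, camera adjusted p = 2.17e-10, and 4.42e-06 with an estimated correlation). The immediate early genes, which respond within minutes to stimulation, were higher in 7 of 7 members with 0 called by edgeR (median 0.40, camera adjusted p = 0.000473), and heat shock genes in 9 of 11 with BAG3 called (median 0.18, adjusted p = 0.000595). Interferon response genes were lower, 8 of 10 in number, with IFI6 (-2.33 ± 0.63) and IFI44 (-2.24 ± 0.54) called and 4 called when adjusted over the list alone (median -0.87, camera adjusted p = 0.00086). Axon guidance genes (median -0.21, camera adjusted p = 0.0034), matrix genes (-0.18, adjusted p = 0.0482) and grey matter astrocyte genes (-0.19, adjusted p = 0.00145) were lower. Myelin genes were lower in 13 of 13 members (median -0.39, adjusted p = 7.6e-16, camera). DCN, a fibroblast marker, was at 0.985 against 3.25 CPM. The largest changes above 20 CPM were those of AGBL5, FOSL2, VEGFA and ID1 (1.28 to 1.58) and of PDE3B, C3, SVIP and ERMN (-1.12 to -1.25). With screened counts 8 genes were called, 5 higher and 3 lower, 6 of them among the 196. There 467 of 12488 genes tested had an unadjusted p below 0.05. Of hypoxia genes PFKFB3 was called there (0.60), while VEGFA (1.41) and HILPDA (0.70) lost their calls. The hypoxia (median 0.60), immediate early (0.49), heat shock (0.22), interferon (-0.97) and axon guidance (-0.16) lists were called there too, the grey matter list was called lower (camera adjusted p = 0.0211) with a median of -0.09 but a mean of 0.05, and the cholesterol synthesis list was called there alone (0.07, camera adjusted p = 0.0137).

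Lumbar and cervical oligodendrocytes differed in 185 genes, 99 higher and 86 lower (edgeR quasi-likelihood, BH). P4HA1, a prolyl hydroxylase of collagen, was at 176.4 ± 47.5 CPM in lumbar and 103.6 ± 28.8 CPM in cervical plates (0.77 ± 0.11, edgeR adjusted p = 8.3e-06), and POLA2, a subunit of DNA polymerase alpha, was higher by 0.67 ± 0.12. COX3, a mitochondrial gene of cytochrome oxidase, was lower (587.9 ± 105 against 989.2 ± 155 CPM, -0.75 ± 0.08, edgeR adjusted p = 6.2e-11). The median mitochondrial share of a kept nucleus's counts was 0.277% in lumbar, 0.505% in cervical and 0.489% in thoracic nuclei. LGALS1, which codes for galectin-1, was lower by a log2 fold change of -1.07 ± 0.19, the cold-responsive RBM3 by -0.75 ± 0.15 and the ribosomal RPL18 by -1.15 ± 0.24. Myelin genes were lower in 10 of 13 members with 0 called by edgeR (median -0.14, camera adjusted p = 5.31e-12, and 2.94e-08 with an estimated correlation). Hypoxia genes were higher in 10 of 12 members (median 0.48, camera adjusted p = 0.000206), with VEGFA called and 2 called when adjusted over the list alone. Neurofilament and axon cytoskeleton genes were lower (median -0.36, 6 of 7 members, adjusted p = 0.000594, camera), and the activated microglia list was lower by a median of -0.03 (adjusted p = 0.0175). The genes with the largest changes above 20 CPM were TENM1, P4HA1, SRPX2 and POLA2 (0.67 to 0.96) and LGALS3BP, LGALS1, ERCC6 and RPL18 (-0.89 to -1.15). With screened counts 15 genes were called, 4 higher and 11 lower, 12 of them among the 185. There 723 of 13504 genes tested had an unadjusted p below 0.05. The myelin (-0.12, camera adjusted p = 5.57e-07), neurofilament (-0.38) and activated microglia (-0.10) lists kept their calls, while the hypoxia list did not.

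**Figure D3:**
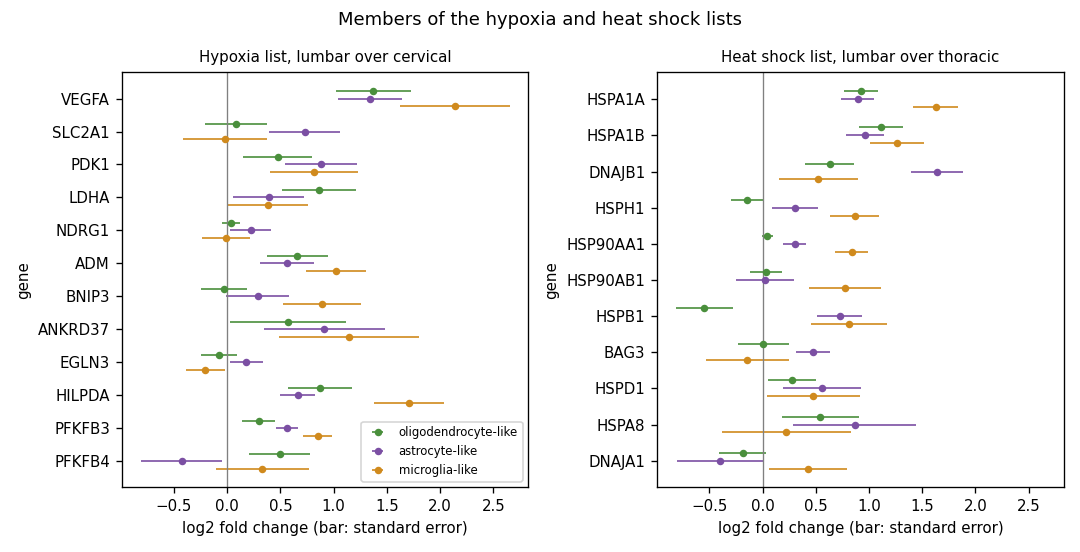
Log2 fold change of each member of the hypoxia list (lumbar over cervical) and the heat shock list (lumbar over thoracic) in oligodendrocyte-, astrocyte- and microglia-like nuclei, with bars for the standard error of the edgeR fit. VEGFA lay at 2.14 in microglia, 1.35 in astrocytes and 1.37 in oligodendrocytes, and HSPA1A at 1.63, 0.89 and 0.92.

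In oligodendrocyte precursors, 207 genes were called higher and 183 lower in lumbar than in cervical plates (edgeR quasi-likelihood, BH), but the leading genes were carried by few plates. CYB5D2 (43.2 ± 61.2 against 5.42 ± 7.46 CPM, 2.98 ± 0.62), D2HGDH, F5 and ATP6AP1 had the largest values above 20 CPM on the lumbar side (2.46 to 2.98), and SLC35F4, IFI44L, GPATCH4 and PANK1 on the cervical side (-3.11 to -4.18), with an SD above the mean in the higher group for each of these 8 genes. Hypoxia genes were higher (median 0.26, 2 of 12 called, camera adjusted p = 0.0093), interferon genes lower (-0.56, 1 of 7 called, adjusted p = 0.0093, and p = 0.0624 with an estimated correlation) and myelin genes lower (-0.35, adjusted p = 0.000968). With screened counts 1 gene was called, the long noncoding RNA LINC00909 at 8.80 against 3.13 with counts as deposited. None of these lists was called there, and 122 of 7451 genes tested had an unadjusted p below 0.05. The screen sets low counts to 0, so the size of 8.80 depends on that floor. Random regroupings of the same plates called a median of 303 genes in precursors, so most single calls there cannot be told from chance. In the same comparison they called a median of 173 genes in microglia, 59 in oligodendrocytes and 55 in astrocytes with counts as deposited, against 0 in each of these 3 classes with screened counts, so in these 3 classes the genes called in both count sets carry the most weight, and adjusted p-values from counts as deposited are too small.

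Cervical and thoracic oligodendrocytes differed in 1680 genes, 324 higher and 1356 lower in cervical plates (edgeR quasi-likelihood, BH). STMN1, which codes for the microtubule regulator stathmin (GRCh38, GENCODE release 29, chromosome 1, 25884181 to 25906991), was at 349 ± 84.3 CPM in cervical and 180.6 ± 57.9 CPM in thoracic plates (0.95 ± 0.12, edgeR adjusted p = 2.39e-08). PRNP, the prion protein gene, was higher by 0.90 ± 0.12 (343.3 against 183.4 CPM, edgeR adjusted p = 9.37e-08). The metallothionein gene MT3 was higher by 0.85 ± 0.13, the chaperone gene HSPA2 by 0.76 ± 0.10 and the complex I gene NDUFS5 by 1.23 ± 0.27. HHLA2, a member of the B7 family of immune ligands, was lower (26.0 ± 11.2 against 69.9 ± 42.8 CPM, -1.43 ± 0.19, edgeR adjusted p = 8.66e-08). An oligodendrocyte cluster with HHLA2 among its leading genes held 85 of 2031 thoracic, 57 of 3758 cervical and 47 of 3322 lumbar oligodendrocytes. NTAQ1, an amidase of N-terminal glutamine, was lower by a log2 fold change of -0.80 ± 0.11, and P4HA1 by -0.70 ± 0.12.

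Myelin genes were higher in cervical oligodendrocytes in 13 of 13 members, with 1 called (median 0.27, camera adjusted p = 2.65e-11). Cholesterol synthesis genes, which feed myelin membranes, were higher in 12 of 17 members with 0 called (0.26, adjusted p = 0.00777, camera). Hypoxia genes were lower (-0.36, 2 of 12 called, camera adjusted p = 0.0136). Lists of other cell types and of the matrix were lower as well: reactive astrocyte (-0.82, camera adjusted p = 4.28e-06), white matter astrocyte (-0.75, adjusted p = 0.0023), grey matter astrocyte (-0.53, adjusted p = 0.000609), axon guidance (-0.47, adjusted p = 3e-05) and extracellular matrix (-0.25, adjusted p = 0.000123). SLC1A2, an astrocyte marker, stood at 16.5 CPM in cervical and 33.3 CPM in thoracic oligodendrocytes, and the microglia marker DOCK8 at 21.8 and 33.8 CPM. SLC1A2 was not particular to astrocytes (765.7 CPM in cervical and 691.8 CPM in thoracic plates), as precursors held 1015 and 967.1 CPM. Largest in size above 20 CPM were the changes of LRRC47, CCNQ, NDUFS5 and PSMD2 (1.19 to 1.26) and of HHLA2, SLC4A4, TENM1 and BNC2 (-1.27 to -1.43). With screened counts 31 genes were called, 16 higher and 15 lower, 29 of them among the 1680. There 970 of 13504 genes tested had an unadjusted p below 0.05. Of these lists the myelin list kept its call (0.09, camera adjusted p = 0.0282), and the activated microglia list was called there alone (0.20, adjusted p = 0.00473).

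Cervical and thoracic astrocytes differed in 669 genes, 180 higher and 489 lower in cervical plates (edgeR quasi-likelihood, BH). CRYAB, a small heat shock protein gene, was at 504.3 ± 154 CPM in cervical and 303.2 ± 120 CPM in thoracic plates (0.73 ± 0.14, edgeR adjusted p = 0.000448). MT2A, a metal-binding metallothionein gene, was higher by 0.83 ± 0.15 (263.8 against 148.4 CPM, edgeR adjusted p = 0.000192). ANGPTL4, an inhibitor of lipoprotein lipase, was lower (173.9 ± 65.3 against 286.6 ± 92.6 CPM, -0.72 ± 0.16, edgeR adjusted p = 0.00262), as was NTAQ1 (-0.78). Heat shock genes were higher in 9 of 11 members, with 3 called (0.40, camera adjusted p = 0.0024, and p = 0.055 with an estimated correlation). White matter astrocyte genes were higher (0.22, 2 of 10 called, camera adjusted p = 2.2e-05), and interferon genes too (0.66, 1 of 10 called, adjusted p = 0.023, and p = 0.055 with an estimated correlation). Hypoxia (-0.27, camera adjusted p = 0.0234, and p = 0.0656 with an estimated correlation), axon guidance (-0.21, adjusted p = 0.0289, and p = 0.055) and myelin genes (-0.26, adjusted p = 0.0289, and p = 0.276) were lower. Changes above 20 CPM were largest for DENR, SLC7A5, GPLD1 and TCEAL4 (1.69 to 1.90) and AGBL5, LOC730100, HHLA2 and AKAP12 (-1.26 to -1.50). AKAP12 is also among the leading genes of the fibroblast-like cluster. With screened counts 13 genes were called, 7 higher and 6 lower, 11 of them among the 669. An unadjusted p below 0.05 was reached by 598 of 12488 genes tested. The hypoxia (-0.36, camera adjusted p = 0.000122) and interferon lists (0.67, adjusted p = 0.00594) were called there too.

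Cervical and thoracic microglia differed in 1282 genes, 517 higher and 765 lower in cervical plates (edgeR quasi-likelihood, BH). HSPA1A, the inducible HSP70 chaperone gene (GRCh38, GENCODE release 29, chromosome 6, 31815464 to 31817946), was at 360 ± 140 CPM in cervical and 109.8 ± 57.9 CPM in thoracic plates (1.71 ± 0.21, edgeR adjusted p = 9.77e-09). The deacetylase gene HDAC9 was higher by 1.19 ± 0.18 (edgeR adjusted p = 1.22e-06). SYTL3 was lower (147 against 262.8 CPM, -0.84 ± 0.25, edgeR adjusted p = 0.0173). Heat shock genes were higher in 10 of 11 members, 4 of them called and 5 when adjusted over the list alone (0.52, camera adjusted p = 3.49e-05). Homeostatic microglia genes were higher in 6 of 6, with CSF1R, the receptor that keeps microglia alive, called (0.70) and 3 when adjusted over the list alone (median 0.88, camera adjusted p = 0.00131).

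MHC class II genes, which present antigen, were higher in 8 of 10 members, with HLA-DRA (0.95), HLA-DRB1 (0.79) and CD74 (0.66) called higher and HLA-DMA (-2.92) called lower in cervical microglia (median 0.50, camera adjusted p = 0.00314). Activated microglia genes were higher (0.52, camera adjusted p = 0.0241, and p = 0.0633 with an estimated correlation). Hypoxia genes were lower in 11 of 12 members, with 3 called (-0.35, camera adjusted p = 0.00575). Axon guidance (-0.47, camera adjusted p = 2.89e-09), grey matter astrocyte (-0.58, adjusted p = 7.01e-08), extracellular matrix (-0.67, adjusted p = 3.49e-05) and reactive astrocyte genes (-0.24, adjusted p = 0.0207) were lower. SLC1A2 stood at 38.7 CPM in cervical and 65.9 CPM in thoracic microglia. The largest changes above 20 CPM were those of ZMYM3, SSU72, PLEKHF2 and IFFO1 (2.28 to 2.61) and of SLC16A10, SH3BP5, FOSL2 and ZNF766 (-2.16 to -3.14). With screened counts 23 genes were called, 16 higher and 7 lower, 16 of them among the 1282. An unadjusted p below 0.05 was reached by 402 of 8423 genes tested. Of these lists the heat shock list kept its call (0.42, camera adjusted p = 0.00139, and p = 0.0557 with an estimated correlation).

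Oligodendrocyte precursors differed in 512 genes between cervical and thoracic plates, 283 higher and 229 lower (edgeR quasi-likelihood, BH). RIOK1, a kinase gene of ribosome assembly, was higher by 3.52 (9.70 with screened counts) and EDEM1, which clears misfolded proteins, by 2.63 (8.56), while LINC00909 was lower (-3.60 and -9.63). In the higher segment the SD over plates exceeded the mean for these genes (RIOK1 39.2 ± 101 CPM). The screen sets low counts to 0, so the larger sizes with screened counts depend on that floor and are not stronger changes. Largest in size above 20 CPM were the changes of C6orf118, FREM3, MFSD4B and GYG1 (4.07 to 5.11) and of UEVLD, PHAX, MAN1A1 and PSMB2 (-2.11 to -2.50). Reactive astrocyte (median -0.81, camera adjusted p = 5.72e-06), matrix (-0.42, adjusted p = 0.0233) and white matter astrocyte genes (-0.09, adjusted p = 0.0127, and p = 0.059 with an estimated correlation) were lower. For 2 lists called lower by camera the median was positive and the mean negative, hypoxia (0.07 and -0.25, adjusted p = 0.0188) and axon guidance (0.10 and -0.07, adjusted p = 0.0233). With screened counts 8 genes were called, 7 higher and 1 lower, 4 of them among the 512, and 0 lists. An unadjusted p below 0.05 was reached by 174 of 7451 genes tested. Random regroupings of the plates called a median of 194 genes with counts as deposited, and 4 of 60 groupings, the real one among them, called at least 8 genes with screened counts.

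Lumbar and thoracic oligodendrocytes differed in 1267 genes, 221 higher and 1046 lower in lumbar plates (edgeR quasi-likelihood, BH). HSPA1A was at 100 ± 29.6 CPM in lumbar and 52.8 ± 23.8 CPM in thoracic plates (0.92 ± 0.16, edgeR adjusted p = 2.9e-05), and its neighbour HSPA1B was higher by 1.11 ± 0.21. STMN1 was higher by 0.76 ± 0.12 and FDFT1, the squalene synthase gene, by 0.63 ± 0.09 (331.3 against 214.7 CPM, edgeR adjusted p = 1.39e-07). COX3 was lower (587.9 against 1028 ± 228 CPM, -0.81 ± 0.08, edgeR adjusted p = 8.02e-12), beside a median mitochondrial share of 0.277% in lumbar and 0.489% in thoracic nuclei, as were HHLA2 (-1.51 ± 0.20) and NTAQ1 (-0.89). Cholesterol synthesis genes were higher in 13 of 17 members, with FDFT1 and MSMO1 called (0.27, camera adjusted p = 0.000908), and myelin genes in 10 of 13 (0.18, adjusted p = 0.0102). Heat shock genes were higher with a median of 0.05 and a mean of 0.25 (2 of 11 called, 3 when adjusted over the list alone, camera adjusted p = 0.0203). Reactive astrocyte (-0.66, camera adjusted p = 3.22e-06), matrix (-0.59, adjusted p = 3.22e-06), grey matter astrocyte (-0.52, adjusted p = 0.00249), axon guidance (-0.35, adjusted p = 6.84e-06) and white matter astrocyte genes (-0.35, adjusted p = 0.0102, and p = 0.0885 with an estimated correlation) were lower. Changes above 20 CPM were largest for DBNL, DHDDS, HSPA1B and TMEM235 (1.10 to 1.20) and HHLA2, PLXNA4, BNC2 and NTRK3 (-1.17 to -1.51). With screened counts 36 genes were called, 10 higher and 26 lower, 27 of them among the 1267, and 0 lists. There 853 of 13504 genes tested had an unadjusted p below 0.05.

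Lumbar and thoracic astrocytes differed in 884 genes, 179 higher and 705 lower in lumbar plates (edgeR quasi-likelihood, BH). CRYAB (GRCh38, GENCODE release 29, chromosome 11, 111908565 to 111923722) was at 645.1 ± 173 CPM in lumbar and 303.2 CPM in thoracic plates (1.09 ± 0.14, edgeR adjusted p = 9.22e-08). The HSP40 gene DNAJB1 was higher by 1.64 ± 0.24 and ID1, a target of BMP signalling, by 2.85 ± 0.43 (64.0 against 8.85 CPM, edgeR adjusted p = 2.04e-06). The early response genes FOS (423.9 ± 110 against 197.2 ± 109 CPM, 1.10 ± 0.21, edgeR adjusted p = 0.00017) and NR4A2 (1.58 ± 0.35) were higher. COX3 was lower (-0.84 ± 0.14, edgeR adjusted p = 1.21e-05), as was COX2 (-0.79), beside a median mitochondrial share of 0.277% in lumbar and 0.489% in thoracic nuclei. HHLA2 (-1.72) and NTAQ1 (-1.06) were lower too.

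Heat shock genes were higher in 10 of 11 members in lumbar astrocytes, 4 of them called (median 0.56, camera adjusted p = 1.8e-08). Immediate early genes were higher in 7 of 7 with 2 called (0.86, camera adjusted p = 2.6e-05), and white matter astrocyte genes in 8 of 10 with 1 called (0.33, adjusted p = 6.61e-07). Axon guidance (-0.42, camera adjusted p = 1.1e-05) and myelin genes (-0.56, adjusted p = 4.54e-16) were lower. The largest changes above 20 CPM were those of ID1, SLC22A3, VAT1L and DNAJB1 (1.64 to 2.85) and of HHLA2, RIMS1, SYNE2 and LOC730100 (-1.29 to -1.72). With screened counts 23 genes were called, 14 higher and 9 lower, 20 of them among the 884. An unadjusted p below 0.05 was reached by 562 of 12488 genes tested. The heat shock (0.53), immediate early (0.77), white matter astrocyte (0.24) and axon guidance (-0.22) lists kept their calls. Called there alone were the lists of cholesterol synthesis (0.58, camera adjusted p = 0.00223), grey matter astrocyte (-0.22, adjusted p = 0.00223) and reactive astrocyte genes (-0.18, adjusted p = 0.0294).

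Lumbar and thoracic microglia differed in 1369 genes, 648 higher and 721 lower in lumbar plates (edgeR quasi-likelihood, BH). HSPA1A was higher by 1.63 ± 0.21 (338.7 ± 127 against 109.8 CPM, edgeR adjusted p = 2.4e-08) and HSP90AA1, the inducible HSP90 gene, by 0.84 ± 0.15. Heat shock genes were higher in 10 of 11 members, 4 of them called and 6 when adjusted over the list alone (0.77, camera adjusted p = 5.51e-07). MHC class II genes were higher in 9 of 10, with HLA-DRB1 (1.14), HLA-DPA1 (1.12), HLA-DRA (1.03) and CD74 (0.66) called (median 0.51, camera adjusted p = 1.86e-05). Activated microglia genes were higher, with CTSB, a lysosomal protease gene (0.79), APOE (0.92) and the integrin gene ITGAX (0.85) among 4 of 11 called (0.52, adjusted p = 0.000714, camera). Axon guidance (-0.47, camera adjusted p = 1.23e-11), matrix (-0.85, adjusted p = 8.42e-09), grey matter astrocyte (-0.50, adjusted p = 2.41e-07), neurofilament (-0.23, adjusted p = 0.00236) and myelin genes (-0.39, adjusted p = 5.7e-07) were lower. Largest in size above 20 CPM were the changes of RAB37, AK6, ZBTB34 and UQCRB (2.42 to 2.60) and of BICC1, SYNE2, CEMIP and LAMA2 (-1.75 to -2.21). BICC1 and LAMA2 are among the leading genes of the fibroblast-like cluster, which held a larger share of thoracic nuclei. The fibroblast marker DCN stood at 1.73 CPM in lumbar and 8.62 CPM in thoracic microglia. With screened counts 15 genes were called, 13 higher and 2 lower, 11 of them among the 1369. There 331 of 8423 genes tested had an unadjusted p below 0.05. Of these lists the heat shock list kept its call (0.55, camera adjusted p = 0.000497).

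Oligodendrocyte precursors differed in 445 genes between lumbar and thoracic plates, 240 higher and 205 lower (edgeR quasi-likelihood, BH). SEPHS1, a gene of selenium metabolism, was higher by 3.59 (8.96 with screened counts), EDEM1 by 2.76 (8.72) and SEMA6D, which codes for an axon guidance protein, by 1.83 ± 0.47 (9.96 ± 1.99). Their SD over lumbar plates exceeded the mean (SEMA6D 47.5 ± 79.4 CPM), and the sizes with screened counts depend on the screen setting low counts to 0. Changes above 20 CPM were largest for C6orf118, CDIPT, MFSD4B and BPHL (3.77 to 4.26) and TRAK2, GNPNAT1, KIFBP and LAMA2 (-2.02 to -2.82). LAMA2 is also among the leading genes of the fibroblast-like cluster. GABA and glycine genes were higher in 6 of 7 members, with 0 called and 4 when adjusted over the list alone (median 0.86, camera adjusted p = 0.023). Reactive astrocyte (-0.76, camera adjusted p = 2.18e-05), axon guidance (-0.04, adjusted p = 0.000593) and myelin genes (-0.14, adjusted p = 0.0131, and p = 0.111 with an estimated correlation) were lower. The matrix list was called lower (camera adjusted p = 0.000593) with a median of 0.16 and a mean of -0.26. With screened counts 8 genes were called, 7 higher and 1 lower, 4 of them among the 445. An unadjusted p below 0.05 was reached by 167 of 7451 genes tested. Random regroupings called a median of 139 genes with counts as deposited. The GABA and glycine list kept its call (1.11, adjusted p = 0.0129, camera), and the myelin list was called higher (0.49, adjusted p = 0.0304, and p = 0.0714 with an estimated correlation).

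HOX genes, which pattern the body axis, were few among the genes used, and 0 of those tested were called between any segments. HOXC4 and HOXD3 were tested in 4 classes and HOXD1 in 3. The values given below are examples from oligodendrocytes. Only genes listed for all 3 segments were used, so a HOX gene listed for some segments only would have been left out. The tests say nothing about such genes. HOXD3 stood at 12.9 CPM in lumbar and 13.0 CPM in cervical oligodendrocytes (-0.01 ± 0.33, edgeR adjusted p = 0.998). HOXD1 stood at 26.9 CPM in cervical and 13.6 CPM in thoracic oligodendrocytes (0.98 ± 0.46, edgeR adjusted p = 0.157). The list of HOX groups 1 to 5 was not called in 9 camera tests (lowest adjusted p = 0.106), and those of groups 6 to 9 and 10 to 13 had too few members to test. Neuropeptide (6 camera tests, lowest adjusted p = 0.766), cholinergic (3, 0.373), preganglionic (12, 0.208) and cell cycle genes (12, 0.165) were not called. Of 234 list tests, 73 were called with the preset correlation of camera and 63 with both correlations, against 26 and 24 of 192 with screened counts.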

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

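The comparisons of both groups of nuclei below were chosen after their clusters had been seen. Nuclei of the cluster that took no name made up a mean of 3.23% of nuclei on thoracic plates (SD 2.05, n = 18), a signal in nuclei that no planned comparison used, against 2 of 7340 cervical (upper limit 0.0984%) and 2 of 6939 lumbar nuclei (upper limit 0.104%). The fibroblast list came closest to naming this cluster, with 2 members passing of the 3 needed. Ependymal-like nuclei, also outside the planned comparisons, made up a mean of 0.292% of nuclei on thoracic plates (SD 0.354), with 0 cervical and 0 lumbar nuclei, counts that allow up to 0.0409% and 0.0432%.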

How the results depend on the processing

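Of the alternatives below, the counts screened or with background subtracted, the clustering on counts as deposited, thoracic plates 1 and 2 left out and the glial shares were chosen after the data had been seen. Comparisons are written LC (lumbar with cervical), CT (cervical with thoracic) and LT (lumbar with thoracic). With the size factors of DESeq2 (RLE), at least 1000 genes per nucleus (which removed no nucleus), at least 20 nuclei per plate, the top 5% of Scrublet scores left out or thoracic plates 1 and 2 left out, each count of called genes stayed within 1.5 times of the reported one, between 175 and 1692 genes. The 242 named gene results gave 3017 values under alternatives, of which 2722 kept direction and side of the threshold, 292 lost the call (107 of them with screened counts), 3 gained it and 0 changed sign. Of 120 class shares under alternatives, 103 kept direction and side. None of these alternatives varied the minimum of genes above the screen alone. Shares of kinds of neuron have no informative alternative, since both settings tried left the same neurons.

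Counts of called genes past 1.5 times of the reported one were as follows, and the cause was not tested except where given. Without the low count filter, which tests 16809 genes, 1420 LC, 1364 CT, 1264 LT in precursors, 388 LC in astrocytes and 776 LC in microglia were called. With the Wald test of DESeq2 the counts were 281 LC in oligodendrocytes, 750 LC, 1164 CT, 1194 LT in precursors and 419 LC, 1047 CT in astrocytes. With nuclei thinned to equal counts, which leaves fewer genes to test, they were 46 LC, 990 CT, 778 LT in oligodendrocytes, 34 LC, 22 CT, 54 LT in precursors, 56 LC, 151 CT, 265 LT in astrocytes and 164 LC, 805 CT in microglia. Fits of only the 2 segments compared, on fewer plates, called 106 LC in oligodendrocytes, 110 LC in precursors, 114 LC, 430 CT in astrocytes and 231 LC in microglia. Background subtraction gave 120 LC in oligodendrocytes, 48 LC, 69 CT, 52 LT in precursors, 96 LC, 416 CT, 527 LT in astrocytes and 128 LC, 531 CT in microglia. Screened counts, which leave fewer counts and genes, gave 15 LC, 31 CT, 36 LT in oligodendrocytes, 1 LC, 8 CT, 8 LT in precursors, 8 LC, 13 CT, 23 LT in astrocytes and 19 LC, 23 CT, 15 LT in microglia. An unadjusted p below 0.05 was there less frequent than chance alone would give in precursors, astrocytes and microglia, and more frequent in oligodendrocytes. Clustering on counts as deposited, which also changed the nuclei kept, gave 1088 LC, 660 CT in microglia. Of list tests 26 were called with screened counts against 73, and 63 with an estimated correlation.

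Plates share numbers between segments, 22, 18 and 18 of them for LC, CT and LT, but the numbers did not pair the plates. The median correlation of deviations between plates of 1 number was 0, -0.001 and -0.003 (range -0.024 to 0.022), 0 pairs lay above 0.1, and 0 plates correlated best with their own number. With the plate number as a replicate block, 34 LC, 832 LT in oligodendrocytes, 2 LC, 67 CT, 70 LT in precursors, 38 LC, 190 CT, 459 LT in astrocytes and 50 LC, 590 CT, 678 LT in microglia were called. With plates paired by number, share differences missed the threshold for neurons (CT 0.185, adjusted p = 0.0836), precursors (LC 0.777, adjusted p = 0.0836, and CT -1.01, adjusted p = 0.0713) and vascular nuclei (CT -0.386, adjusted p = 0.0746) in the permutation test.

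Without thoracic plates 1 and 2 the CT difference of precursors was -0.742 (permutation test, adjusted p = 0.101). Clustering on counts as deposited, which also changed the nuclei kept, turned the sign of the precursor CT (0.258) and LT (0.843), astrocyte CT (4.03) and microglia LC differences (-12.9). Of these, precursor LT (adjusted p = 0.0137), astrocyte CT (9e-05) and microglia LC (3.6e-05) gained a call in the permutation test. The precursor LC (0.585, adjusted p = 0.059) and microglia LT differences (0.0350, adjusted p = 0.994) lost their calls there in the permutation test. As shares of the 4 glial classes, whose total leaves out fibroblast-like and other nuclei, oligodendrocytes turned sign in LT (-0.128). Precursors in LC (0.792, adjusted p = 0.0631), astrocytes in LT (0.794) and microglia in CT (0.529) and LT (0.323) lost their calls, and astrocytes in CT gained one (-2.88). Not run were at least 20 nuclei per plate for precursors, which too few plates hold, and each gene count of neurons and vascular cells. Depth was least for precursors among the classes with gene tests, with 303 to 428 nuclei per segment.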

Other observations

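The share tests of this paragraph, the tests of shared RNA by the screen and of depth in oligodendrocytes, the screened tests of the hypoxia list, the spread between gene and class pairs and the regroupings of plates were chosen after the results had been seen. Fibroblast-like nuclei, which in the cord lie in meninges and around vessels, made up 7.86% ± 1.89 (SD) of thoracic, 3.32% ± 1.01 of cervical and 1.43% ± 0.647 of lumbar nuclei, and each pair of segments differed (permutation test, p = 1e-05, the smallest the resamples can give, adjusted p = 3.6e-05). Schwann-like nuclei, the myelin-forming cells of nerve roots, made up 1.51% ± 0.611 of thoracic nuclei against 0.661% ± 0.547 of cervical (permutation test, adjusted p = 0.00012) and 0.795% ± 0.421 of lumbar ones (adjusted p = 0.000247). Lymphocyte-like nuclei made up 0.347% of lumbar and 0.162% of thoracic nuclei (permutation test, adjusted p = 0.0352). Ependymal-like nuclei, which line the central canal, numbered 14, all from the thoracic segment and spread over 9 plates.

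The cluster that took no name held 161 nuclei, of which 157 were thoracic. It was led by IGFBP5, an insulin-like growth factor binding protein gene, BMPER, a regulator of BMP signalling, GADL1, SPTLC3 and PHLDB2. The fibroblast list matched this cluster best, with 2 members passing where a name needed 3. Its leading markers were SLC4A4 and the fibroblast-like cluster's markers FBLN1 and DCN. Its share was 3.23% ± 2.05 of thoracic nuclei against 0.0268% of cervical and 0.0286% of lumbar nuclei (permutation test, adjusted p = 3.6e-05 for both). Among microglia, a cluster led by CD83 and HIF1A held 133 of 1399 lumbar, 81 of 1461 cervical and 49 of 837 thoracic nuclei.

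Of the genes called between cervical and thoracic oligodendrocytes, 1356 were higher in thoracic plates. A difference in depth stays open as the cause. With nuclei thinned to equal counts the median change was 1.026 times its size, past the bound set against this explanation. But random thinning leaves a gene's expected share of counts unchanged, so such a value was likely in either case and cannot decide. Shared RNA of a plate stays open: in screened counts the change was 1.421 times its size, a value beyond the bound set against this explanation, but that bound was wrong, since the screen left a median of 15.73% of these genes' counts against 86.55% for other genes, 639 of the 1356 were no longer tested and 13 were called. In the background wells, which no label marks as empty, these genes were higher in thoracic plates by a median log2 ratio of 0.349. This value lay between both bounds, against 0.908 in oligodendrocytes and -0.038 for other genes. A real difference between the levels of the cord was not tested apart from preparation.

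With screened counts, 3 genes (CCDC186, LINC00486 and NTAQ1) were higher in thoracic than cervical plates in at least 2 classes, and 9 in thoracic over lumbar plates, among them COX2, COX3, HHLA2, POLDIP3 and TSNAXIP1. Shared RNA stays open: with a larger multiple of the background screened out the median change was 0.855 of its size, past the bound set against it, but that bound left out the spread of 25 gene and class pairs (0.387 to 1.723, lower quartile 0.733), and the genes had been picked in screened counts. Separate preparation or counting of the segments cannot be told apart from a difference of cord level, as changes against thoracic plates correlated across genes between classes (median r = 0.157 over 12 pairs of classes, from 0.072 to 0.239) and the labels give no batch.

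Hypoxia genes were higher in lumbar than cervical microglia. Without the cluster led by CD83 and HIF1A the median change was 0.879 of its size (0.73 against 0.83, with 4 of 12 members called), which argues against a larger share of that cluster as the cause. For the 8 members tested in both count sets, which had a median of 83.86% of their counts above the screen, the screened change was 0.863 of its size, which argues against shared RNA for these. For the other 4, HILPDA and ADM among them, the median was 20.09% and shared RNA stays open. The median mitochondrial share stood at 0.277% in lumbar, 0.489% in thoracic and 0.505% in cervical nuclei. Hypoxia genes were also lower in cervical than in thoracic microglia. For the members called against cervical plates, log2 fold changes of lumbar over thoracic microglia were 1.26 (VEGFA), 0.82 (PFKFB3), 0.05 (HILPDA) and -0.01 (ADM). A difference in tissue handling was not tested, nor was a biological one.

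For each count of called genes, 60 groupings of the plates into groups of the same sizes were drawn, the real one included. With counts as deposited 1 grouping, the real one, called as many genes in each of the 12 comparisons. This is the lowest rank that 60 groupings allow, and it was not adjusted over the comparisons. It argues against chance for the counts without excluding it. For precursors, lumbar with cervical, 390 and 378 lie too close to tell the count from chance. The real and highest other counts were 185 and 86 (lumbar with cervical), 1680 and 69 (cervical with thoracic) and 1267 and 171 (lumbar with thoracic) in oligodendrocytes, 390 and 378, 512 and 273, and 445 and 193 in precursors, 196 and 106, 669 and 142, and 884 and 58 in astrocytes, and 458 and 240, 1282 and 126, and 1369 and 136 in microglia. Regrouped plates thus called many genes, the cause of which was not tested, and the adjusted p-values of single genes with counts as deposited are too small. This was most so for precursors in each comparison (medians of 303, 194 and 139) and for microglia in lumbar with cervical plates (173). In microglia the medians were 56 for cervical with thoracic and 82 for lumbar with thoracic plates. In oligodendrocytes they were 59 (lumbar with cervical), 35 (cervical with thoracic) and 27 (lumbar with thoracic). In astrocytes the medians were 55 for lumbar with cervical, 60 for cervical with thoracic and 24 for lumbar with thoracic plates. With screened counts the real grouping alone called as many genes in 10 of the 12 comparisons, which argues against chance with the same limits. The real and highest other counts there were 15 and 1, 31 and 3, and 36 and 5 in oligodendrocytes, 8 and 4 in precursors (lumbar with thoracic), 8 and 2, 13 and 7, and 23 and 3 in astrocytes, and 19 and 1, 23 and 5, and 15 and 5 in microglia. Chance is not argued against for precursors in the other comparisons, where 6 of 60 groupings called at least 1 gene (highest other 2, lumbar with cervical) and 4 of 60 called at least 8 (highest other 9, cervical with thoracic).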
